A study of Arabidopsis thaliana with 24 samples.

How the data were processed

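RNA was measured in rosettes of Arabidopsis thaliana on 24 Affymetrix ATH1 arrays, 1 plant RNA sample per array. Per the labels, plants grew at 22 °C with a 14 h photoperiod, were sprayed with water or 300 µM BTH 2 days before collection, and were collected at 4 weeks. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared from 15 µg of it. The titles of the samples gave genotype, treatment and replicate number, and placed the arrays in 6 groups of 4: Col with water, Col with BTH, mil4 with water, mil4 with BTH, mil4 sid2 with water and sid2 with water. The titles call the replicates biological, and how the plants of a replicate were grown or pooled is not given in the sources used here.

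The values deposited by the authors are probe-set intensities on a linear scale, in 1 table with 24 columns of 22810 probe sets, all of which were used. From the values, each array had been scaled to a 2% trimmed mean of 500 (500.0 to 500.1), and no other normalization between arrays was apparent. The software, background correction, summary of probes and detection calls are not given in the sources used here. Per the file headers, a further file per array records the hybridization and scan settings, from which the day (4 days), the run (8 runs) and the module of the fluidics station were taken as batches. Low intensities carry mostly background, and a trimmed-mean scaling assumes that the total signal is alike on all arrays. For arrays, precision is limited by their number, here 4 per group.

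The design fixed in advance expected log2 values. The values were linear, so its fallback was used, log2(intensity + 16), and fold changes on that scale understate the changes of dim probe sets. Array medians lay between 151.9 and 185.0, a ratio of 1.22, and the arrays were not rescaled. The 64 Affymetrix control probe sets were left out, which left 22746. Pearson's r between arrays ran from 0.953 to 0.9808 within groups, with a highest value of 0.9806 between groups, and no arrays were identical.

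Gene names came from the platform annotation supplied with the value table. It gave 1 gene for 13513 probe sets, several for 503 and none for 8730 of those tested, which are unnamed here and not without a gene. Of the 13513, 13436 matched the RefSeq gene table of assembly TAIR10.1, which was used for names and gene order alone. They cover 13286 loci, and for the 144 loci with several probe sets the brightest one was used.

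Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 24 arrays, contrasts.fit and eBayes, 2-sided), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were mil4 against Col with water, BTH against water in Col and in mil4, the genotype by BTH interaction, sid2 against Col, mil4 sid2 against mil4, mil4 sid2 against sid2, and the mil4 by sid2 interaction. Overlaps were set beside independent lists, beside 20 simulations of unchanged groups with the same shared arrays, and beside fits with separate parts of the Col water arrays. Gene lists with at least 3 measured genes, 6 lists and 48 tests, were tested with camera at its preset correlation and at an estimated one, and with fry, each adjusted over the 48 tests. The 21 lists held 245 genes of salicylic acid synthesis, signalling and response, secretion, tryptophan and camalexin, jasmonate and ethylene, photosynthesis, cell death and senescence, oxidative stress, pattern-triggered immunity, cysteine-rich kinases, auxin, aliphatic glucosinolates, heat shock, touch and cold, the circadian clock, and markers of floral, root, guard, trichome, vascular and dividing cells. Plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

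The genes named for a comparison were the 8 largest rises and 8 largest falls past the threshold with a single gene name and no overlap between the 4 arrays of each group. For interactions the 5 largest each way were taken, without the overlap rule. Of each list up to 4 measured genes with the largest changes were taken, passing or not, and ICS1, PR1, PR2 and PR5 were to be given always. The text describes part of the genes so chosen. Family tests, the comparison of mil4 with Col under BTH and that of mil4 sid2 with Col were added after the data were seen.

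The replicate numbers were checked for pairing from the correlation of the deviations of same-numbered arrays from their group means, over 9657 probe sets. For Col with water and Col with BTH all 4 pairs had correlations of 0.17 to 0.34, all 8 arrays correlated best with their own number, and all 4 pairs shared a run. These arrays were therefore treated as pairs in an added fit of the Col arrays alone and in the chance splits of BTH in Col. The main fit did not use the pairs. The pairing comes from the data and the runs, since the labels do not say what a number stands for. In the other comparisons at least 1 pair lay under 0.1.

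The tests were run on simulated data made from the mean over all arrays and the within-group spread of each probe set, with 200 of 22746 probe sets changed. The changed ones were drawn from the brighter probe sets, so recovery among dim ones was not measured. Of 2-fold changes, 85% were recovered for mil4 against Col, 90% and 88% for BTH in Col and mil4, 89% for sid2 against Col, 86% for mil4 sid2 against mil4 and 94% against sid2, and 55% and 67% for the genotype by BTH and mil4 by sid2 interactions. Of 4-fold changes 98% to 100% were recovered, and 3.1% to 7.8% of calls were false. Alternatives tried were pseudocounts of 1 and 64, quantile normalization, the probe sets brighter than the median, leaving out probe sets that can bind several transcripts, the replicate number, day and module as blocks, fits of the groups compared alone, trend and robust eBayes, array weights, a 2-fold minimum, and each array left out in turn.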

Results

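Gene expression was measured in rosettes of 4-week-old Arabidopsis thaliana plants on 24 Affymetrix ATH1 arrays, in 6 groups of 4. Wild-type plants (Col) and plants carrying mil4, a mutation in MILDEW-INDUCED LESIONS 4, were sprayed with water or with 300 µM BTH, 2 days before collection. BTH (benzothiadiazole) is a synthetic compound that acts in plants like salicylic acid, a defence hormone. sid2 plants and mil4 sid2 double mutants were sprayed with water. The sid2 mutation lies in ICS1, which encodes isochorismate synthase, the enzyme behind most of the salicylic acid made after pathogen attack. The title of the series places MIL4 in the salicylic acid response, and the groups allow its effect to be read with and without BTH and with and without SID2. The labels give the 4 arrays of each group as biological replicates.

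Probe-set intensities ran from 0.1 to 47321.3, and the array medians from 151.9 to 185.0. Between 9.64% and 17.97% of the probe sets of an array lay under an intensity of 16, the lowest share being that of sid2 replicate 1. The 3′ to 5′ signal ratio of GAPDH, a sign of RNA quality, averaged 0.854 ± 0.115 (SD, n = 4) in Col with water, 1.03 ± 0.436 in mil4 with water, 1.09 ± 0.017 in mil4 sid2 and 1.16 ± 0.057 in sid2. In mil4 with water it was 1.648 on replicate 4 and 0.651 to 0.98 on the other arrays. For ubiquitin the group means ran from 1.79 in mil4 with BTH to 2.56 in mil4 sid2, and for actin from 9.11 in mil4 sid2 to 12.1 in mil4 with BTH. Principal component 1 carried 21.2% of the variance and parted the BTH arrays, with scores of 31.7 to 66.3, from the water arrays. Component 2 carried 12.4%, and on it the 4 Col water arrays (35.9 to 46.0) lay above every other array. Of the probe sets, 388 differed between Col water and each of the 5 other groups, against 8 to 215 for the other groups. Neither ICS1, PR1, PR2, PR5 nor MIL4 had a probe set that carried its name, so no level of these genes is given and the genotypes were not checked on the arrays.

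**Figure D1:**
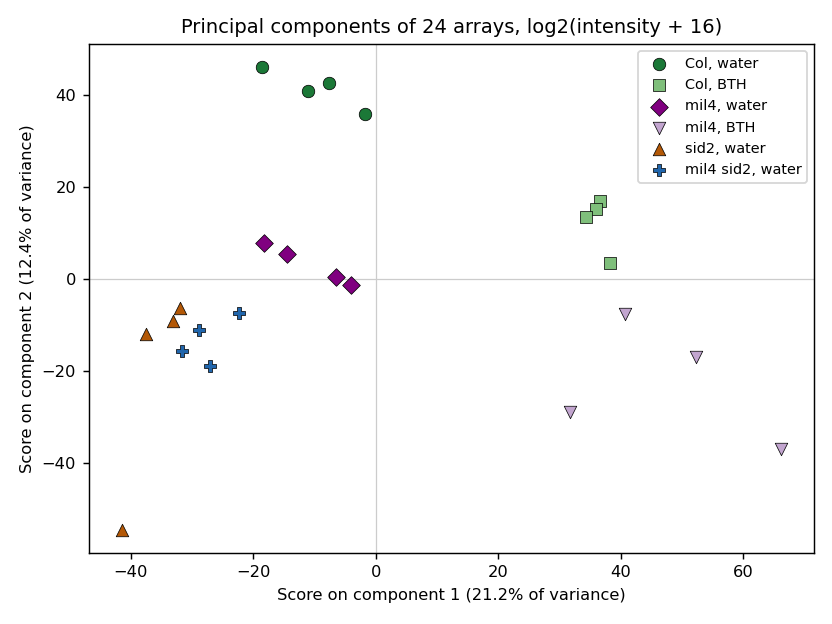
Scores of the 24 arrays on principal components 1 and 2 of log2(intensity + 16), 1 point per array, with the groups marked by colour and shape. The 4 Col water arrays lie between 35.9 and 46.0 on component 2, and sid2 replicate 1 lies at -54.6.

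In Col, BTH raised AT2G44240, the largest rise of a named gene, 44.8-fold (log2 fold change 5.48, SE 0.49, adjusted p = 2.25e-07, n = 4 arrays per group). CHI, a chitinase gene, rose by 4.12 on the log2 scale (SE 0.35), SAL2, which encodes a bisphosphate nucleotidase, 12.6-fold (3.66, SE 0.30), LUP5, a triterpene synthase gene, 9.41-fold (3.23, SE 0.37) and AMY1, an alpha-amylase gene, 8.76-fold (3.13, SE 0.17). AT2G44240 and LUP5 lay close to background with water (means of 5.24 and 5.1), so the size of their rises depends on the pseudocount. ORA47, a transcription factor gene that acts on jasmonate and abscisic acid synthesis, fell 11.4-fold (-3.51, SE 0.31, adjusted p = 1.87e-07). Its mean was 11.25 in Col with water and 7.73 with BTH, but also 6.78, 7.68 and 7.08 in mil4, sid2 and mil4 sid2 with water. So its fall may reflect Col with water standing apart from all groups. The cold-response genes COR15A and COR15B fell 5.14-fold (-2.36, SE 0.42) and 3.89-fold (-1.96, SE 0.23), and UGT76E11, a glycosyltransferase gene, fell 4.08-fold (-2.03, SE 0.29). The comparison asks how wild-type rosettes respond to the salicylic acid analogue. Among 22746 probe sets, 2886 passed an adjusted p of 0.05 in limma, 1528 higher and 1358 lower, and 483 rose and 184 fell at least 2-fold. Under quantile normalization the split was 1349 higher and 1492 lower. The largest rise of a probe set without a gene name was 26.8-fold.

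Genes tied to salicylic acid rose with BTH in Col. The 2 measured genes of the salicylic acid response list, which has 14, both passed: GRXC9, a glutaredoxin gene that the hormone induces, rose 2.5-fold (log2 fold change 1.32, SE 0.27, adjusted p = 0.00179, n = 4 per group), and WRKY53, a transcription factor gene of senescence and defence, rose 1.83-fold (0.87, SE 0.23, adjusted p = 0.0146). SAG101, a partner of EDS1 in immune signalling and the 1 measured gene of 15 on the salicylic acid synthesis and signalling list, rose 2.16-fold (1.11, SE 0.23, adjusted p = 0.00183). BIK1, a kinase gene of pattern-triggered immunity, rose 1.53-fold (0.61, SE 0.14, adjusted p = 0.00469), the 1 of 3 measured genes on that list to pass. Counts adjusted over the list alone were 2 of 2, 1 of 1 and 1 of 3. The call of WRKY53 was lost without Col water replicate 4 (adjusted p = 0.0623), Col BTH replicate 3 (0.0531) or Col BTH replicate 4 (0.0507).

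All 4 measured genes of the 18 on the endoplasmic reticulum secretory list rose with BTH in Col, also 4 of 4 adjusted over the list alone. ERDJ3B, a chaperone gene, had a log2 fold change of 1.13 (SE 0.14, adjusted p = 7.61e-06, n = 4 per group), CRT1B, a calreticulin gene, 0.68 (SE 0.10), CNX2, a calnexin gene, 0.66 (SE 0.11), and SEC61A, a gene of the protein translocation channel, 0.38 (SE 0.08, adjusted p = 0.004). As a set they stood above the other genes (camera, adjusted p = 2.32e-05 over 48 list tests, and adjusted p = 0.029 with an estimated correlation). Their mean log2 fold change was 0.70, 0.76 and 0.69 within hybridization days 1, 2 and 3, and the list kept its call with day as a block (adjusted p = 2.48e-05 over 36 tests). PDF1.2, a defensin gene that jasmonate induces, fell 6.46-fold (log2 fold change -2.69, SE 0.84, adjusted p = 0.0368) and was the 1 of 3 measured jasmonate and ethylene genes to pass, against 2 of 3 adjusted over the list alone. That call was lost without Col water replicate 1 (adjusted p = 0.138) or 3 (0.052) and without Col BTH replicate 1 (0.0711), 2 (0.0681), 3 (0.0923) or 4 (0.06), and with run as a block (0.0777). PDF1.2B was at -2.35 (adjusted p = 0.12, but 0.0483 among probe sets brighter than the median and 0.049 with array weights) and THI2.1, a thionin gene, at -0.42 (adjusted p = 0.5). STZ, a zinc finger gene that touch and cold induce, fell 2.34-fold (-1.23, SE 0.29, adjusted p = 0.00547). It averaged 11.59 in Col with water and 10.36 with BTH, but 8.85, 8.99 and 9.0 in mil4, sid2 and mil4 sid2 with water. FAMA, a gene of guard cell formation, was 1.38-fold lower (-0.47, adjusted p = 0.0383), a call lost without any array of the 2 groups except Col BTH replicate 1 (adjusted p up to 0.154).

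The values above for BTH in Col come from the main fit, which ignores the pairing of same-numbered Col water and Col BTH arrays. The pairs were used in an added fit, and fry was not run with them. With the pairs as a block, in a fit of the Col arrays alone chosen after the data were seen, 1057 probe sets passed, and 977 of them were among the 2886. SAG101, ERDJ3B, CRT1B and the genes with the largest changes kept their calls, apart from PDF1.2 (adjusted p = 0.0619). GRXC9 (0.0577), WRKY53 (0.12), CNX2 (0.0553), SEC61A (0.106), BIK1 (0.0529), STZ (0.086) and FAMA (0.151) missed the threshold with their fold changes unmoved. In that fit camera gave the secretory list an adjusted p of 9e-04 over the 6 lists that could be tested (adjusted p = 0.253 with an estimated correlation) and the jasmonate and ethylene list 0.0345 (adjusted p = 0.455 with an estimated correlation). Without pairs, adjusted over the same 6 tests, they had 2.9e-06 and 0.103 (adjusted p = 0.00388 and 0.445 with an estimated correlation). With hybridization day as a block 3042 probe sets passed, and 100%, 99% and 99.7% of the 2886 kept their direction within days 1, 2 and 3. Probe sets called from pooled arrays tend to keep their direction in parts of the same arrays. Such shares, by day, run or module, are therefore no separate test here or in the other comparisons. No module of the fluidics station held both water and BTH arrays of Col. With module as a block 893 probe sets passed, and PDF1.2, GRXC9, WRKY53, SAG101, SEC61A, BIK1, STZ and FAMA did not (adjusted p from 0.0855 to 0.294). Fitted without the other groups, WRKY53 (0.0927), SEC61A (0.0564), STZ (0.0552) and FAMA (0.0724) lost their calls.

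In mil4, BTH raised many of the genes it raised in Col. AT2G44240 rose 21-fold (log2 fold change 4.39, SE 0.49, n = 4 arrays per group), AMY1 10.9-fold (3.45, SE 0.17, adjusted p = 1.28e-10), CHI 10.9-fold (3.44, SE 0.35) and LUP5 8.13-fold (3.02, SE 0.37). AT3G13610, which encodes an oxygenase of coumarin synthesis, rose 11.6-fold (3.54, SE 0.60), and UGT73D1, a glycosyltransferase gene, 9.71-fold (3.28, SE 0.47). LUP5 and UGT73D1 lay close to background in mil4 with water (means of 5.29 and 5.31), so the size of their rises depends on the pseudocount. The falls were smaller, led by AT1G30250 at 3.66-fold (-1.87, SE 0.23). AT1G12010 fell as well, by 1.83 on the log2 scale (SE 0.31), to a mean of 4.97 that stands for an intensity under 16, so the size of its fall depends on the pseudocount. This comparison asks whether the mutant still responds to the analogue. In limma 3968 probe sets passed, 2200 higher and 1768 lower, with 763 rises and 164 falls of at least 2-fold. Under quantile normalization the split was 1753 higher and 2135 lower. Without mil4 BTH replicate 3, 2637 probe sets passed. In both genotypes 1794 probe sets changed in the same direction and 49 in opposite directions, where independent lists of these sizes would share 253.3 and 250.1.

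The salicylic acid response genes rose in mil4 too, WRKY53 by 7.21-fold (log2 fold change 2.85, SE 0.23, adjusted p = 1.33e-07, n = 4 per group) and GRXC9 by 2.81-fold (1.49, SE 0.27, adjusted p = 0.000486), and SAG101 rose 2.05-fold (1.03, SE 0.23). The secretory genes again rose in 4 of 4 cases, ERDJ3B by 1.24 on the log2 scale, CRT1B by 0.71, CNX2 by 0.53 and SEC61A by 0.50 (camera adjusted p = 6.58e-05, and adjusted p = 0.029 with an estimated correlation). Their mean was 0.95, 0.63 and 0.70 within days 1, 2 and 3, and with day as a block the adjusted p was 6.78e-05. IGPS, a gene of tryptophan synthesis and the 1 measured of 10 on the tryptophan and camalexin list, rose 1.8-fold (0.85, SE 0.13, adjusted p = 7.32e-05). GH3.3, which encodes an enzyme that conjugates auxin, rose 2.63-fold (1.39, SE 0.25), the 1 of 3 measured auxin genes to pass, against 2 of 3 adjusted over the list alone. BIK1 rose 1.82-fold (0.87, SE 0.14) and STZ 3.18-fold (1.67, SE 0.29). THI2.1 was 2.09-fold higher (1.07, adjusted p = 0.0276), a call lost without mil4 water replicate 1 (0.0713) or 3 (0.0807) or mil4 BTH replicate 3 (0.119), while PDF1.2 was at -0.01 (adjusted p = 0.997) and PDF1.2B at 0.11 (0.963). With day as a block 4187 probe sets passed, and 99.7%, 97.1% and 100% of the 3968 kept their direction within days 1, 2 and 3. No module held both water and BTH arrays of mil4. With module as a block 1379 passed, and GRXC9 (0.0554), SAG101 (0.0755), CNX2 (0.102) and THI2.1 (0.347) did not.

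**Figure D2:**
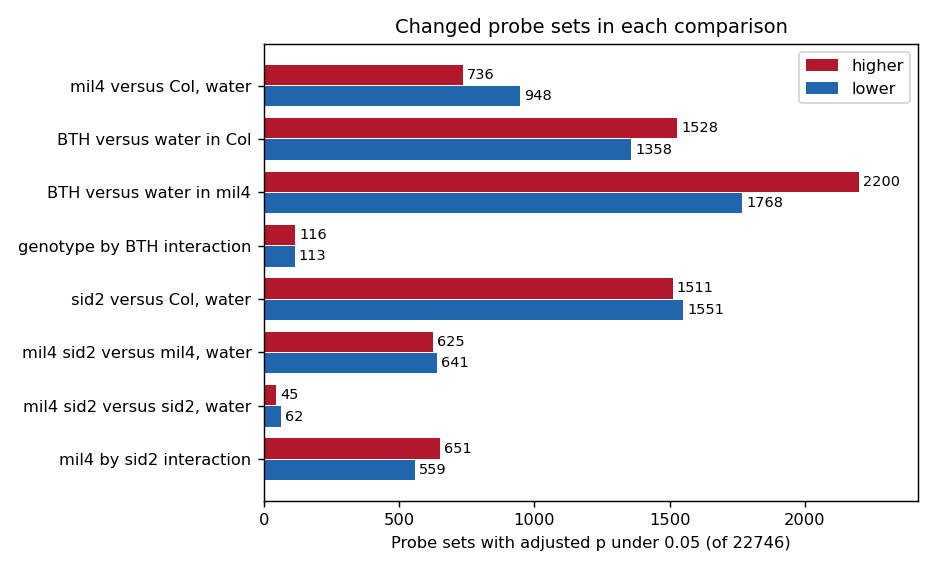
Number of probe sets, of 22746, with an adjusted p under 0.05 in limma in each comparison, with red bars for higher and blue bars for lower values in the group named first. Counts run from 45 higher and 62 lower between mil4 sid2 and sid2 to 2200 higher and 1768 lower with BTH in mil4.

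ORA47, which was lower with BTH than with water in Col, differed in mil4 by 3.38 in log2 fold change (SE 0.44, adjusted p = 0.000323, n = 4 arrays in each of 4 groups). Its mean was 11.25 in Col with water and 7.73 with BTH, and in mil4 it was low before BTH, at 6.78 and 6.64. STZ fell in Col and rose in mil4, a difference of 2.90 (SE 0.40, adjusted p = 0.000667), and WRKY53 rose more in mil4 by 1.98 (SE 0.33, adjusted p = 0.00275), from a lower level with water (7.61 against 9.66) to a like one with BTH (10.46 and 10.53). AT1G72920 differed by 2.18 (SE 0.42), and on the other side AT1G50040 by -3.52 (SE 0.57), AT4G16563 by -2.41 (SE 0.49), AT5G25240 by -2.35 (SE 0.46) and AT3G06070 by -2.24 (SE 0.35). GRXC9 (0.17, adjusted p = 0.941), SAG101 (-0.08, 0.971) and ERDJ3B (0.11, 0.912) showed no difference past the threshold. The interaction asks whether mil4 alters the response itself. In limma 229 probe sets passed, 116 with a higher and 113 with a lower response in mil4 (93 and 112 under quantile normalization), and 149 without mil4 BTH replicate 3. Over 29 other settings the count ran from 115 to 407. Of the 229, 181 had also differed between mil4 and Col with water, a difference that enters the interaction with its sign turned, and 74 were among the 388 in which Col with water stood apart from each other group. With day as a block 240 passed, and 100%, 98.7% and 100% of the 229 kept their direction within days 1, 2 and 3. Of the 10 genes with the largest differences, 3 lost their calls without 1 of 10 to 15 of the 16 arrays and are not described. AT4G16563 (adjusted p = 0.0796) and AT5G25240 (0.0613) lost theirs in a fit of the 4 groups alone.

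The jasmonate and ethylene list had a higher response to BTH in mil4 as a set (camera adjusted p = 0.0246, and adjusted p = 0.532 with an estimated correlation), although none of its 3 measured genes passed alone. PDF1.2 was at 2.68 (SE 1.19, adjusted p = 0.435), PDF1.2B at 2.45 (0.585) and THI2.1 at 1.49 (0.169), and 1 of 3 passed adjusted over the list alone. PDF1.2B was read from a probe set that can bind several transcripts, and its means in Col with water, Col with BTH, mil4 with water and mil4 with BTH (8.83, 6.48, 9.41 and 9.52) followed those of PDF1.2 (9.35, 6.66, 9.87 and 9.86). Without such probe sets the list had 2 measured genes and was not tested, and 4 list tests passed in place of 5. The list call was lost without Col water replicate 1 (adjusted p = 0.12), Col BTH replicate 1 (0.0588), mil4 water replicate 1 (0.1) or 3 (0.0945), or mil4 BTH replicate 3 (0.085). With day as a block its adjusted p was 0.0474. Within days 1, 2 and 3 the list's mean log2 fold change with BTH was -1.26, -3.51 and -1.26 in Col and 2.75, -2.67 and 0.73 in mil4.

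**Figure D3:**
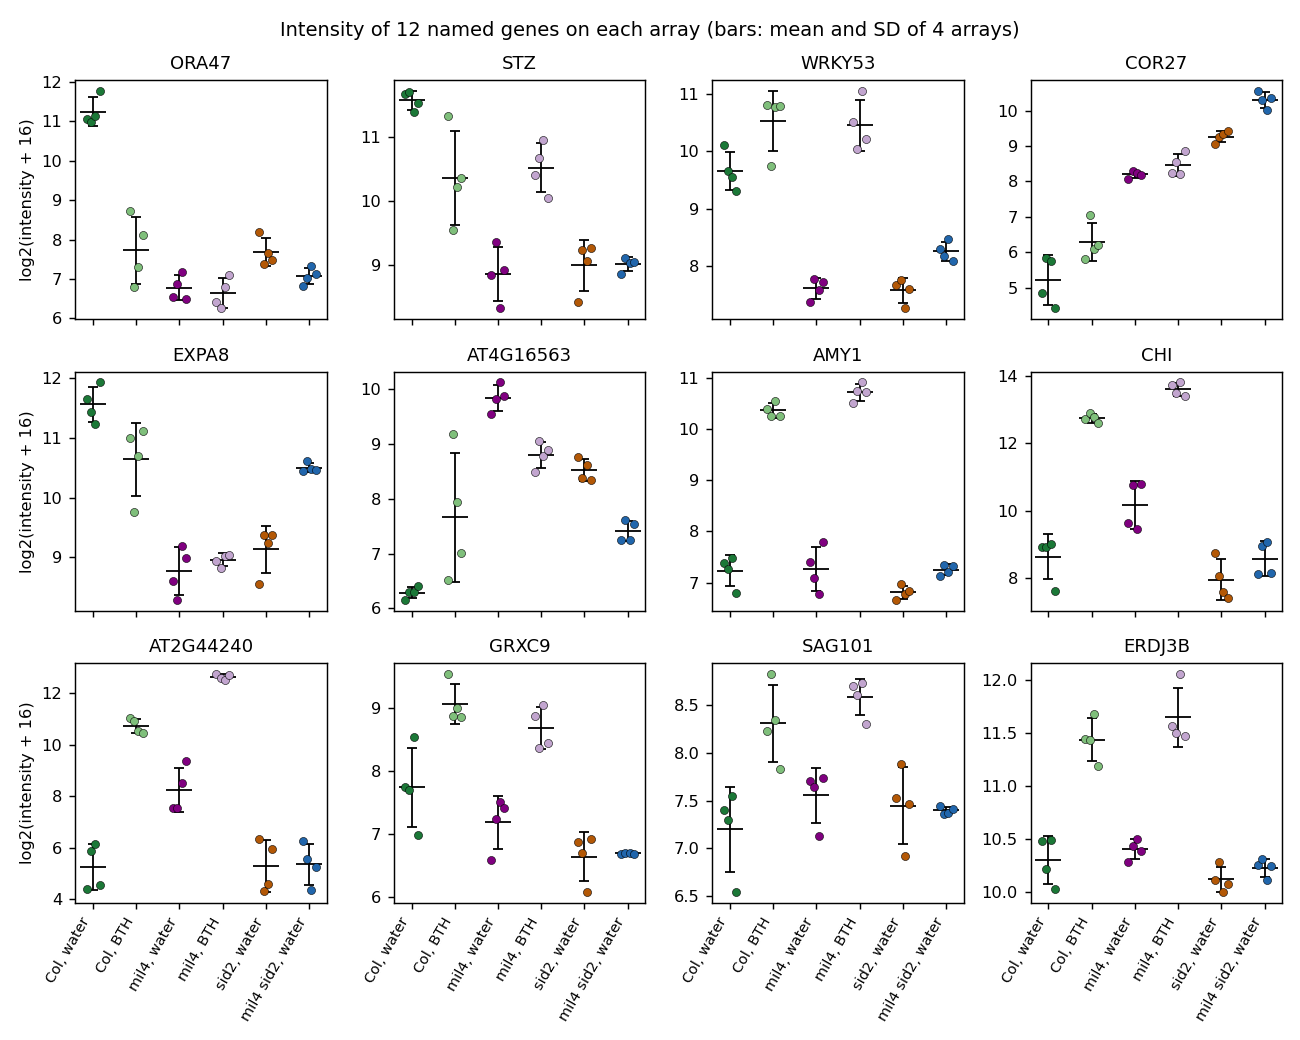
Intensity of 12 named genes, as log2(intensity + 16), with 1 point per array and bars for the mean and SD of the 4 arrays of each group. ORA47 and STZ are highest in Col with water, while AMY1, CHI and AT2G44240 are highest with BTH in both genotypes.

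Among water-treated plants, ORA47 was 22.1-fold lower in mil4 than in Col (log2 fold change -4.47, SE 0.31, adjusted p = 2.3e-08, n = 4 arrays per group). This was the largest change among the genes named here at the pseudocount of 16. STZ was 6.66-fold lower (-2.74, SE 0.29), and EXPA8, an expansin gene of cell wall loosening, 6.93-fold lower (-2.79, SE 0.25). AT2G15020 was lower too (-4.11, SE 0.36), but its mean of 4.34 in mil4 stood for an intensity under 16, so the size of its change depends on the pseudocount (-6.14 with 1 and -2.54 with 64). AT4G16563, which encodes an aspartyl protease, was 11.8-fold higher in mil4 (3.56, SE 0.35), AT2G44240 8-fold (3.0, SE 0.49) and COR27, a cold-response and clock-output gene, 7.87-fold (2.98, SE 0.27). The size of the last 2 changes depends on the pseudocount as well, since their means in Col (5.24 and 5.22) lay close to background. The cell wall genes EXLA1, expansin-like, and XTH33, a xyloglucan hydrolase gene, were 6.64-fold (2.73, SE 0.39) and 6.24-fold (2.64, SE 0.40) higher. The comparison asks what mil4 changes in plants that were not challenged. In limma 1684 probe sets passed, 736 higher and 948 lower in mil4, 228 and 293 of them at least 2-fold. With day as a block 1593 passed, and 99.9%, 99.1% and 99.8% of the 1684 kept their direction within days 1, 2 and 3. Within modules 1 and 3, which held both groups, 100% and 99.9% kept it.

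The measured genes of the salicylic acid lists, few of those listed, did not move together between mil4 and Col with water. WRKY53 was 4.14-fold lower in mil4 (log2 fold change -2.05, SE 0.23, adjusted p = 6.47e-06, n = 4 per group), GRXC9 was at -0.55 (SE 0.27, adjusted p = 0.285) and SAG101 at 0.36 (0.461). Of the genes described above that BTH raised in Col, some had higher means in mil4 with water than in Col. These were AT2G44240 (8.24 against 5.24, and 5.36 in mil4 sid2), CHI (10.17 against 8.63, and 8.57) and SAL2 (8.03 against 6.86, and 7.53). LUP5 (5.29 and 5.1) and AMY1 (7.27 and 7.23) were alike in mil4 and Col. None of the 4 secretory genes passed, with values from -0.07 for SEC61A to 0.14 for CNX2 (camera adjusted p = 0.911). GI, a clock gene and the 1 measured of 12 on the circadian list, was 1.34-fold higher (0.42, SE 0.10, adjusted p = 0.0129, and 0.000582 adjusted over the list alone), and lost its call in a fit of both groups alone (0.125). Both measured genes of the aliphatic glucosinolate list were lower, UGT74B1 at -0.58 (adjusted p = 0.0328) and BCAT4 at -0.54 (0.0301). UGT74B1 lost its call without Col water replicate 1 (0.0925), 2 (0.104) or 3 (0.0983) or mil4 water replicate 2 (0.0607), 3 (0.0845) or 4 (0.0922). BCAT4 lost its call without Col water replicate 2 (0.0597), 3 (0.0735) or 4 (0.0883) or mil4 water replicate 1 (0.113), 2 (0.107) or 3 (0.0677), and with day as a block (0.0541). In a fit of both groups alone UGT74B1 (0.149) and BCAT4 (0.172) lost their calls, and with module as a block UGT74B1 did (0.0533). In a test of families of genes with a shared symbol, chosen after the data were seen, 11 of 47 measured UGT glycosyltransferase genes were lower in mil4 (23.4%, against 3.4% of 13286 named genes, 1-sided Fisher's exact test, adjusted p = 2.69e-05 over 78 tests). They include UGT78D1, UGT78D2, UGT84A3 and UGT76E11. The family kept its call under quantile normalization (10 genes, adjusted p = 7.62e-05) and lost it without mil4 water replicate 4 (6 genes, adjusted p = 0.124). That array stood apart. Over the brighter probe sets the SD of its deviations from the group mean was 0.317, against 0.184 to 0.22 for the other mil4 water arrays. Its array weight was 0.5.

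The changes with mil4 and with BTH in Col overlapped. Of the probe sets that passed in both, 627 changed in the same direction (309 higher, 318 lower) and 41 in opposite directions, where independent lists would give 106 and 107.6. ORA47 and STZ were lower and AT2G44240 was higher in both. Both comparisons are against Col with water. The 388 probe sets in which it differed from each of the 5 other groups are among the 627 by definition, so their inclusion is no evidence. Without them 239 are left (a count made after the data were seen). ORA47 and STZ averaged 11.25 and 11.59 in Col with water and at most 7.73 and 10.52 in any other group. Separate Col arrays do not remove a difference that all 4 share. The fold changes correlated across probe sets, which are not independent replicates, at r = 0.48, and 0.50 arose in simulations of unchanged groups that shared the 4 Col water arrays. The covariance was 0.0885 against 0.0364 in the simulations. With separate pairs of Col water arrays for each comparison, 247 to 297 probe sets changed in the same direction over 6 splits, where independent lists would give 36.8 to 49.8. Without Col water replicate 4 the overlap was 414. With module as a block it was 236, and it was 610 with day as a block.

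In sid2, salicylic acid response genes were lower than in Col. GRXC9 was 2.14-fold lower (log2 fold change -1.10, SE 0.27, adjusted p = 0.00755, n = 4 arrays per group) and WRKY53 4.25-fold lower (-2.09, SE 0.23, adjusted p = 2.13e-06), 2 of 2 also adjusted over the list alone. ORA47 was 11.8-fold lower (-3.56, SE 0.31) and STZ 6.06-fold (-2.60, SE 0.29). AT2G15020 was lower (-4.06, SE 0.36), again with an intensity under 16 in the mutant (mean 4.39). COR27 was 16.6-fold higher (4.05, SE 0.27), AT4G33980 12.3-fold (3.63, SE 0.39) and MCCA, a gene of leucine breakdown, 5.23-fold (2.39, SE 0.17). COR27 and AT4G33980 lay close to background in Col (means of 5.22 and 5.33), so the size of their changes depends on the pseudocount. The comparison asks what loss of SID2 changes without a challenge. In limma 3062 probe sets passed, 1511 higher and 1551 lower. All sid2 and mil4 sid2 arrays were hybridized on day 4 and all Col and mil4 arrays on days 1 to 3, so day and genotype cannot be told apart here. With day as a random block (correlation 0.017) 2948 passed. Module 3 held both groups and within it 99.8% of the 3062 kept their direction. With module as a block 1858 passed. GRXC9 lost its call in a fit of both groups alone (0.0866).

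Of the secretory genes, 3 of 4 passed as lower in sid2, also 3 of 4 adjusted over the list alone: CRT1B at -0.42 (SE 0.10, adjusted p = 0.00421, n = 4 per group), CNX2 at -0.36 (0.0384) and SEC61A at -0.26 (0.041), with ERDJ3B at -0.18 (0.423). CNX2 lost its call without Col water replicate 1 (adjusted p = 0.0689), 2 (0.108) or 3 (0.077) or sid2 replicate 1 (0.0507), 2 (0.0692) or 3 (0.117). SEC61A lost its call without Col water replicate 1 (0.119), 2 (0.0756) or 4 (0.0865) or sid2 replicate 1 (0.0843), 2 (0.0781) or 3 (0.0925), and under quantile normalization (0.0699). As a set the list was lower (camera adjusted p = 0.0239, and adjusted p = 0.252 with an estimated correlation), a call lost without sid2 replicate 3 (0.0527), under quantile normalization (0.0822) and among probe sets brighter than the median (0.115). In a fit of both groups alone CRT1B (0.0595), CNX2 (0.112) and SEC61A (0.187) lost their calls, and with module as a block CNX2 (0.19) and SEC61A (0.193) did. IGPS was 1.4-fold lower (-0.48, SE 0.13, adjusted p = 0.0122), and lost its call without Col water replicate 1 (0.0509) and in a fit of both groups alone (0.0792). GH3.3 was 2.38-fold higher (1.25, SE 0.25, adjusted p = 0.00138) and GI 1.55-fold higher (0.63, SE 0.10, adjusted p = 0.000196). UGT74B1 and BCAT4 were 2.24-fold (-1.16, SE 0.16) and 1.49-fold lower (-0.57, SE 0.15), and BCAT4 lost its call with module as a block (0.078). The GAPDH 3′ to 5′ ratio, 1.16 in sid2 against 0.854 in Col, moved with the same groups.

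mil4 and sid2 changed many of the same probe sets relative to Col with water. Of those that passed in both, 1286 changed in the same direction, 524 higher and 762 lower, among them ORA47, STZ, WRKY53 and AT2G15020 (lower) and COR27, AT3G59350 and EXLA1 (higher). The 388 in which Col with water differed from each of the 5 other groups are among the 1286 by definition, and without them 898 are left. Opposite changes numbered 6, and independent lists would give 113.5 and 113.2. Across probe sets the fold changes correlated at r = 0.683 against 0.503 in simulations of unchanged groups with shared Col arrays, and the covariance was 0.1342 against 0.0366. With separate pairs of Col water arrays for each comparison 638 to 721 probe sets changed in the same direction, where independent lists would give 37.8 to 52.4.

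Adding sid2 to mil4 lowered several genes that mil4 had raised. AT2G44240 was 7.39-fold lower in mil4 sid2 than in mil4 (log2 fold change -2.88, SE 0.49, adjusted p = 0.0013, n = 4 arrays per group), AT4G16563 5.39-fold (-2.43, SE 0.35), EXLA1 4.22-fold (-2.08, SE 0.39) and EXO, a gene of cell expansion, 4.06-fold (-2.02, SE 0.43). EXO had been 5.1-fold higher in mil4 than in Col (2.35, SE 0.43), where its 4 arrays with water varied widely (SD 1.35). In sid2 alone AT4G16563 (mean 8.53), EXLA1 (12.07) and EXO (11.11) also lay above Col with water (6.29, 9.8 and 10.25), while AT2G44240 (5.29 and 5.24) was alike. AT2G44240 fell to 5.36 in mil4 sid2, close to background, so the size of its fall depends on the pseudocount. GTR1, a glucosinolate and nitrate transporter gene, was 3.95-fold lower (-1.98, SE 0.16, adjusted p = 3.85e-07). COR27 was 4.32-fold higher (2.11, SE 0.27), and EXPA8, lower in mil4 than in Col, was 3.32-fold higher (1.73, SE 0.25). Of the secretory genes CRT1B (-0.52, SE 0.10, adjusted p = 0.00243) and CNX2 (-0.54, SE 0.11, adjusted p = 0.00636) were lower, 2 of 4 also adjusted over the list alone, with SEC61A at -0.08 and ERDJ3B at -0.17 (camera adjusted p = 0.00386 for the list, and adjusted p = 0.122 with an estimated correlation). WRKY22, a transcription factor gene of pattern-triggered immunity, was 1.86-fold lower (-0.90, SE 0.20, adjusted p = 0.00902). The largest fall of a probe set without a gene name was 27.8-fold. The comparison asks what loss of SID2 changes in mil4 plants. Of the 1684 probe sets that differed between mil4 and Col, 238 were called here in the opposite direction and 156 in the same one, in comparisons that share the mil4 arrays. Between mil4 sid2 and Col, which shares the Col arrays, 1099 of the 1684 were called in the direction of mil4 and 10 in the opposite one. In limma 1266 probe sets passed, 625 higher and 641 lower, with 84 rises and 177 falls of at least 2-fold. The split depended on the setting, at 466 and 705 under quantile normalization, 225 and 384 in a fit of both groups alone, 205 and 385 with module as a block, and 1008 and 849 with array weights. Without mil4 water replicate 2 the count was 814, without mil4 sid2 replicate 2 it was 807 and without mil4 sid2 replicate 4 it was 829. All mil4 sid2 arrays lay on day 4, apart from the mil4 arrays, and with day as a random block 1166 passed. Within module 1, which held both groups, all 1266 kept their direction, and with module as a block 590 passed but not WRKY22 (0.0536). In a fit of both groups alone CNX2 (0.0648), CRT1B (0.0517) and WRKY22 (0.0789) lost their calls.

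In the absence of SID2, mil4 changed few probe sets. Between mil4 sid2 and sid2, AT1G13650 was 2.98-fold lower with mil4 (log2 fold change -1.58, SE 0.22, adjusted p = 0.00256, n = 4 arrays per group), and AT5G48490 (-1.11, SE 0.13), AT1G68440 (-1.11, SE 0.18) and AT5G44050 (-1.08, SE 0.18) were 2.11-fold to 2.17-fold lower. EXPA8 was 2.57-fold higher (1.36, SE 0.25, adjusted p = 0.0158), a call lost without mil4 sid2 replicate 2 (0.0717) or sid2 replicate 1 (0.0709). WRKY53 was at 0.69 (SE 0.23, adjusted p = 0.223). In limma 107 probe sets passed, 45 higher and 62 lower, and 2542 had an unadjusted p under 0.05. The count fell to 39, 24, 48 and 63 without mil4 sid2 replicates 1, 2, 3 and 4, and to 41, 62 and 50 without sid2 replicates 1, 2 and 3. Of the 16 genes with the largest changes, the 4 named first kept their calls without each array in turn. All these arrays shared day 4, where the day block gave 121. Within runs 7 and 8 and within modules 2 and 4 all 107 probe sets kept their direction, with run as a block 75 passed, and with module as a block 21. AT5G44050 (0.0668) and EXPA8 (0.0588) lost their calls with module as a block. A fit of both groups alone called 0 probe sets in limma, with 2330 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0886.

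The effect of mil4 differed between plants with and without SID2 for EXPA8, which was lower in mil4 than in Col and higher in mil4 sid2 than in sid2, a difference of 4.15 in log2 fold change (SE 0.35, adjusted p = 5.92e-07, n = 4 arrays in each of 4 groups). ORA47 (3.86, SE 0.44), STZ (2.75, SE 0.40) and WRKY53 (2.74, SE 0.33, adjusted p = 2.59e-05) differed in the same direction. AT4G16563 (-4.67, SE 0.49, adjusted p = 7.95e-06), EXLA1 (-4.34, SE 0.55) and XTH33 (-3.32, SE 0.57), which mil4 had raised, differed in the opposite one. Each of these genes had also changed in sid2 against Col, in the direction of mil4. ORA47, STZ and WRKY53 were high in Col with water (11.25, 11.59 and 9.66) and lower in mil4 (6.78, 8.85 and 7.61), sid2 (7.68, 8.99 and 7.57) and mil4 sid2 (7.08, 9.0 and 8.26). This interaction asks whether the effect of mil4 differs between plants with and without SID2. It cannot tell whether the changes of mil4 require SID2, since a probe set that sid2 alone changes as mil4 does can pass too. In limma 1210 probe sets passed, 651 above and 559 below 0 (399 and 419 with module as a block), and 1190 with day as a block. The interaction holds the differences of mil4 and of sid2 from Col with their signs turned, and 949 of the 1210 had been called in the opposite direction between mil4 and Col and 934 between sid2 and Col. Over all probe sets the fold change of mil4 against Col correlated with that of mil4 sid2 against sid2, which shares no array with it, at r = -0.091 (jackknife SE 0.029 over arrays, rho = -0.076). Calls in both numbered 14 in the same and 37 in opposite directions, where independent lists would give 4 and 3.9.

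**Figure D4:**
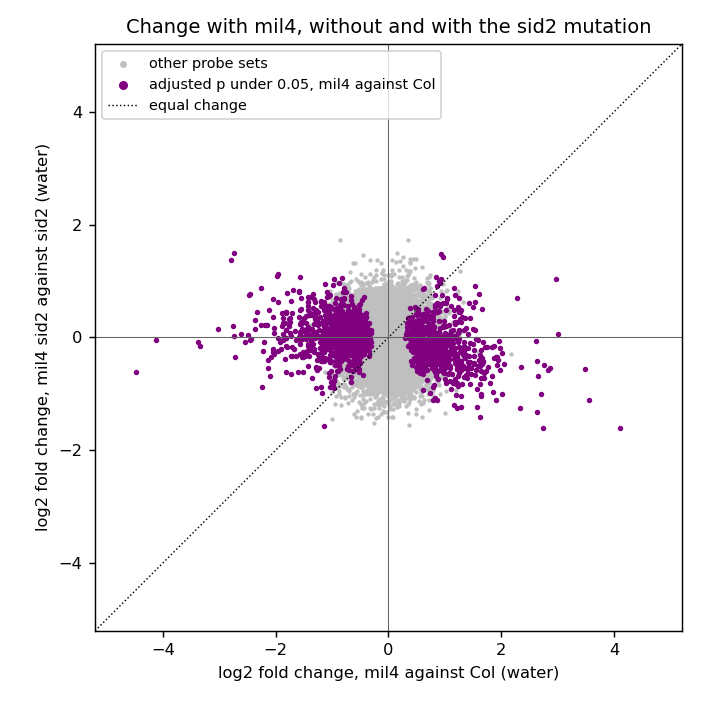
Log2 fold change of each of 22746 probe sets between mil4 and Col (horizontal axis) and between mil4 sid2 and sid2 (vertical axis), all with water. The 1684 probe sets that differed between mil4 and Col are purple and spread along the horizontal axis, with r = -0.091 over all probe sets.

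Most genes of the lists chosen before the data were examined had no probe set that carried their name, and 32 of 245 were measured. No list other than the secretory and the jasmonate and ethylene lists passed camera as a set in any comparison. In fry, which tests whether the genes of a list move on balance in 1 direction, 5 of the 48 tests passed, the secretory list with BTH in Col (adjusted p = 8.5e-09) and mil4 (7.44e-09), for sid2 against Col and for mil4 sid2 against mil4 (0.000228 each), and the auxin list with BTH in mil4 (0.0404, against 0.328 in camera). A further 6 had an unadjusted p under 0.05 alone, among them the jasmonate and ethylene list in the genotype by BTH interaction and with BTH in Col (adjusted p = 0.119 each). In the photosynthesis list 3 of 24 were measured, and LHCB4.2, a light-harvesting gene, passed in 1 comparison, BTH in mil4 (log2 fold change -0.36, adjusted p = 0.0476). That call was lost without any array of the 2 groups other than mil4 water replicate 3 (adjusted p up to 0.147), under quantile normalization (0.139), in a fit of both groups alone (0.0998) and with day (0.0501) or module (0.436) as a block. WRKY22 was lower there as well (-0.59, adjusted p = 0.0445), a call lost without any array other than mil4 water replicate 1 and mil4 BTH replicate 1 (adjusted p up to 0.148), with array weights (0.101), in a fit of both groups alone (0.154) and with day (0.0557) or module (0.22) as a block. Of the cell death and senescence list 2 of 13 were measured, SAG29 and WRKY6, and neither passed in any comparison over all probe sets. WRKY6 with BTH in mil4 (0.67, SE 0.24, adjusted p = 0.0595) passed adjusted over the list alone (1 of 2), with a pseudocount of 64 (0.0284), with trend and robust eBayes (0.0419) and without mil4 BTH replicate 2 (0.00875), and SAG29 with BTH in Col (1.14, adjusted p = 0.247) passed without Col BTH replicate 4 (0.0405). No comparison called the 2 measured genes of 16 on the oxidative stress and detoxification list, also 0 of 2 adjusted over the list alone. Of markers of other cell types, EXPA7 of root hairs was the 1 measured root gene of 7 and passed in none, and of 8 guard cell and stomatal genes 3 were measured, FAMA in the BTH comparison in Col being the single call, with SPCH passing there without Col BTH replicate 1 (0.0313). The lists of cysteine-rich kinases, heat shock, floral, trichome, vascular and dividing cell genes had 0 measured members, so these cell types were not assessed here. The touch, cold and handling list had 1 of 7 (STZ) and the circadian list 1 of 12 (GI).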

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

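Chance splits of the arrays were planned, and the other tests of explanations in this part were chosen after the results were seen. The response to BTH differed between mil4 and Col for 229 probe sets, and the effect of mil4 differed between plants with and without SID2 for 1210 (limma, test of the difference itself). In the first, the difference in log2 fold change was 3.38 for ORA47, 2.90 for STZ, 2.18 for AT1G72920 and 1.98 for WRKY53. It was -3.52 for AT1G50040, -2.41 for AT4G16563, -2.35 for AT5G25240 and -2.24 for AT3G06070. In the second it was 4.15 for EXPA8, 3.86 for ORA47, 2.75 for STZ and 2.74 for WRKY53, and -4.67 for AT4G16563, -4.34 for EXLA1 and -3.32 for XTH33. For AT2G15020 it was 4.07, a value set by a level close to background in mil4 (4.34), sid2 (4.39) and mil4 sid2 (4.35) alike, which leaves no room for a further fall. Without mil4 BTH replicate 3 the first count was 149.

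Each comparison was set beside other splits of the same arrays into groups of the same sizes. For mil4 against Col 1684 probe sets passed and at most 2 in another split, for BTH in mil4 3968 and 5, for sid2 against Col 3062 and 3, for mil4 sid2 against mil4 1266 and 2, and for mil4 sid2 against sid2 107 and 3. In each of these 1 of 35 splits, the real one, gave as many. That share is under 0.05 and argues against chance in each comparison taken alone. It is the smallest that 35 splits allow, and it was not adjusted over the comparisons. Splits that mix differing groups also have a wider spread, which lowers their counts. For mil4 sid2 against sid2 chance is not excluded, since a fit of both groups alone called 0 probe sets in limma (lowest adjusted p = 0.0886). The Col arrays are pairs, so for BTH in Col the real split was set beside those that also part all 4 pairs. These are 8 with the real one, too few for a share under 0.05, and the real one gave 2886 with 0 as the highest other. The other splits of the 35 keep at least 1 pair together, and gave at most 12. For the mil4 by sid2 interaction 1 of 100 splits gave as many as 1210, with 38 as the highest other. These splits exchange arrays among all 4 groups, so they ask whether the groups differ at all. They cannot exclude chance for the interaction itself. For the genotype by BTH interaction 7 of 100 splits gave at least 229, so chance cannot be excluded by that count. The highest other, 2569, put 3 mil4 BTH arrays and Col BTH replicate 4 in 1 group, and such a count points to a structure of the samples, the difference between BTH and water. When arrays were exchanged between genotypes within each treatment, a test added after that result, 4 of 100 splits gave as many, with 917 as the highest other. Neither set of splits for this interaction kept the pairs of Col arrays, so neither settles whether chance gave the count.

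The first pattern weighed is that mil4 and sid2 shared 1286 changes against Col with water, while Col with water stood apart from all groups. A single Col water array does not account for it, since at least 1060 shared changes were left without each in turn, nor do the shared arrays alone, since at least 638 were left with separate pairs of Col arrays, where independent lists would give at most 52.4. For the day of the mil4 arrays, 99.1% or more of the shared probe sets kept their direction within each day. These were called from the same arrays, which favours that agreement, so it cannot decide on the day. With day as a block the number of calls between mil4 and Col changed little, but the shared changes were not counted in that fit. The day of the sid2 arrays cannot be told apart from genotype, since 0 days held both sid2 and Col water arrays, and a difference of the Col plants that lasts in part stays open, since under BTH the mil4 effect had a slope of 0.36 on that with water (0.30 to 0.44 without each array, over probe sets picked for the latter, which lowers it) and the same sign in 86.4%. Handling or time of day of the Col water plants, of which 1 of 7 touch and cold genes and 1 of 12 clock genes were measured, and a shared action of both mutations stay open and may both contribute.

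The second pattern is that mil4 changed 107 probe sets where sid2 was mutated against 1684 where it was not. A wider spread of the sid2 arrays would leave the effects in place and lose only calls, but over the 1684 the slope of the mil4 effect in sid2 on that in Col was -0.11 (-0.12 to -0.10 without each array). For Col water arrays that stand apart the values go both ways. On one side, sid2 differed from Col as mil4 did, with a slope of at least 0.76 where each comparison had separate Col water arrays. On the other, the mil4 effect under BTH, measured without Col water arrays, was for the most part not seen in sid2 (slope 0.06, 0.05 to 0.08 without each array, over 748 probe sets, 59.9% with the same sign). These probe sets were picked for the mil4 effect under BTH, which lowers the slope. They were kept fixed as arrays were left out, although 431 passed without mil4 BTH replicate 3, so the range leaves out that uncertainty. A small part of the mil4 effect under BTH was seen in sid2. Calls in both numbered 18 in the same and 7 in opposite directions, where independent lists would give 1.8 and 1.7. Of the 1684, 97.3% kept their sign between sid2 and Col and 94.2% between mil4 sid2 and Col (slopes 0.96 and 0.85, with shared Col arrays). The slope of 0.06, lowered by that picking, leans only weakly against unusual Col water plants as the sole cause, and the 18 calls in the same direction do not. The slope also sets sid2 plants with water beside BTH plants. So unusual Col water plants, a change that sid2 makes already and to which mil4 adds little, and a need for SID2 stay open and may each contribute.

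The third pattern is that sid2 replicate 1 stood apart, at -54.6 on principal component 2 against -12.0 to -6.3 for the other sid2 arrays (ratio of gap to range 0.882), with an array weight of 0.35. Dim probe sets alone do not account for it, since over the brighter ones its deviations were 1.47 times those of the other sid2 arrays (1.27 times over the dim ones). An array of another group is argued against, since 0 other groups lay nearer to it than its own (distance 0.736, against 0.781 to mil4 sid2, a gap of 0.046 with a jackknife SE of 0.018). The same gap was 0.07 to 0.1 for the other sid2 arrays and -0.14 to -0.113 for those of mil4 sid2. The array also had a median intensity of 185.0 (154.6 to 160.4 on the other sid2 arrays) and 9.64% of probe sets under 16 (15.6% to 16.87%). Its actin 3′ to 5′ ratio was 14.47 (6.883 to 9.96), while those of GAPDH and ubiquitin lay within the range of the others. A sample from outside these groups, or a difference in the plants or preparation of this array, may underlie the pattern and was not tested.

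The remaining results have 1 array far from the other 3 of its group, as the ratio of its gap to the range of the group. Of 227 groups tested 16 passed the critical value of Dixon's test, and chance alone marks about 1 in 20. In Col with water, replicate 4 was low for CHI (7.63 against 8.93 to 9.02, ratio 0.932) and UGT74B1 (10.15 against 10.78 to 10.84, 0.922), and replicate 1 was high for PDF1.2 (11.32 against 8.45 to 8.91, 0.84). In Col with BTH, replicate 2 was low for WRKY53 (9.75 against 10.77 to 10.81, 0.966) and replicate 3 high for AT3G06070 (11.01 against 10.50 to 10.58, 0.849). In mil4 with water, replicate 3 was low for SAG101 (7.13 against 7.64 to 7.74, 0.84) and AT1G72920 (5.27 against 6.19 to 6.38, 0.8294) and had the highest median intensity (158.8 against 152.2 to 153.1, 0.864), and replicate 4 was high for AT3G06070 (11.33 against 10.28 to 10.43, 0.863). In mil4 with BTH, replicate 3 was high for ERDJ3B (12.06 against 11.47 to 11.56, 0.844), BIK1 (10.38 against 9.71 to 9.77, 0.906) and THI2.1 (7.92 against 7.02 to 7.16, 0.842), and in median intensity (175.7 against 170.4 to 171.1, 0.868). In mil4 sid2, replicate 1 was low for AT1G68440 (8.09 against 8.54 to 8.57, 0.943) and replicate 2 for XTH33 (6.88 against 7.08 to 7.09, 0.959).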

How the results depend on the processing

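The alternatives were planned, apart from the fit of the Col arrays alone, the run as a block and the fit without sid2 replicate 1 and mil4 water replicate 4, which were chosen after the data were seen. No gene result that passed, in the main fit or in the alternative, reversed its direction. The direction of the lists, and of genes that passed in neither fit, was not compared. The balance of higher and lower calls turned in some settings, as for BTH in Col and in mil4 under quantile normalization. Of 3457 values of the 161 gene results that passed, 3163 stayed past the threshold and 294 did not, and of 4642 values of 207 gene results that had not passed, 31 did. Of 1552 values of 48 list tests, 8 lost the call. Counts for the main comparisons stayed within 1.5 times of the reported ones except as follows, and the cause was not tested unless named.

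With a pseudocount of 1 the correlation of the mil4 effects with and without SID2 was -0.042, and with 64 it was -0.146, with 362 probe sets in the genotype by BTH interaction. Among probe sets brighter than the median, where fewer were tested, the interaction had 389, mil4 sid2 against sid2 303, the correlation was -0.19 and 3 list tests passed in place of 5. With trend and robust eBayes the interaction had 407 and mil4 sid2 against sid2 246, and with array weights the interaction had 350. With only the groups compared, so with fewer arrays for the spread, mil4 against Col had 956, BTH in mil4 2155, the genotype by BTH interaction 115, sid2 against Col 1691, mil4 sid2 against mil4 609, the overlap of mil4 and BTH 399, and mil4 sid2 against sid2 0 in limma, with 2330 at an unadjusted p under 0.05. With module as a block BTH in Col had 893, BTH in mil4 1379, sid2 against Col 1858, mil4 sid2 against mil4 590, mil4 sid2 against sid2 21, the overlap 236 and the correlation was -0.151. A minimum of 2-fold, which by construction keeps fewer, left 521 for mil4 against Col, 667 and 927 for BTH in Col and mil4, 847 for sid2 against Col, 261 and 35 for mil4 sid2 against mil4 and sid2, 730 for the mil4 by sid2 interaction and 139 for the overlap. Without both sid2 replicate 1 and mil4 water replicate 4, mil4 sid2 against sid2 had 37. That fit also ended the calls of UGT74B1 in mil4 (adjusted p = 0.0602), WRKY22 with BTH in mil4 (0.137), SEC61A in sid2 (0.0832) and EXPA8 in mil4 sid2 against sid2 (0.0743), and run as a block those of FAMA with BTH in Col (0.0808), WRKY22 with BTH in mil4 (0.0654) and PDF1.2 with BTH in Col (0.0777).

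With the replicate block over all 24 arrays the counts were 1669 for mil4 against Col, 2908 and 3968 for BTH in Col and mil4, 202 and 1206 for the interactions with BTH and sid2, 3090 for sid2 against Col, 1253 and 73 for mil4 sid2 against mil4 and sid2, and 617 for the overlap, and 5 list tests passed. Of the genes described, PDF1.2 with BTH in Col (adjusted p = 0.0567), WRKY22 with BTH in mil4 (0.0509) and CNX2 in sid2 (0.0545) lost their calls under it, and the replicate block changed no other call among them. Outside Col the numbers are only shared, with pair correlations from -0.10 to 0.22, and at most 4 of 8 arrays correlated best with their own number. The paired fit of the Col arrays alone gave 1057 for BTH in Col.

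Leaving out each array in turn gave 1312 to 1612 for mil4 against Col, 2172 to 2689 and 2637 to 3823 for BTH in Col and mil4, 149 to 292 for the genotype by BTH interaction, 2466 to 2814 for sid2 against Col, 807 to 1328 and 24 to 105 for mil4 sid2 against mil4 and sid2, 1016 to 1211 for the mil4 by sid2 interaction, 414 to 634 for the overlap, 4 to 5 list tests and a correlation of -0.103 to -0.072. Counts moved by over 1.5 times without mil4 BTH replicate 3 (2637 and 149), Col water replicate 4 (overlap 414), mil4 water replicate 2 (814 for mil4 sid2 against mil4) and mil4 sid2 replicates 2 and 4 (807 and 829). For mil4 sid2 against sid2 they did so without mil4 sid2 replicates 1 to 4 (39, 24, 48, 63) and sid2 replicates 1 to 3 (41, 62, 50). Quantile normalization moved the median log2 fold change by at most 0.084 in size, a fall for BTH in mil4. Day could not be fitted as a fixed block for sid2 against Col and mil4 sid2 against mil4, run only for the BTH comparisons, their interaction and mil4 sid2 against sid2, and list tests were not run with trend and robust eBayes.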

Other observations

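All tests in this part were chosen after the data were seen. Under BTH, mil4 and Col differed in part as they did with water. AT3G13610, an oxygenase gene of coumarin synthesis, was 7.45-fold higher in mil4 (log2 fold change 2.90, SE 0.60, adjusted p = 0.00819, n = 4 arrays per group), AT1G26390 6.25-fold (2.64, SE 0.46), AT1G33950 4.99-fold (2.32, SE 0.38) and COR27 4.49-fold (2.17, SE 0.27). EXPA8 was 3.2-fold lower (-1.68, SE 0.25, adjusted p = 0.000611) and AT2G15020, near background in mil4, was lower too (-2.40, SE 0.36). In limma 748 probe sets passed, and 431 without mil4 BTH replicate 3. Of the 748, 314 had changed in the same direction between mil4 and Col with water and 14 in the opposite one, in comparisons that share no array, where independent lists would give 28.1 and 27.3.

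Between mil4 sid2 and Col with water 3095 probe sets passed (2452 to 2782 without each array in turn). COR27 was 34-fold higher (log2 fold change 5.09, SE 0.27, adjusted p = 2.1e-10, n = 4 arrays per group), AT4G33980 20-fold (4.32, SE 0.39) and MCCA 4.47-fold (2.16, SE 0.17), while ORA47 was 18-fold lower (-4.17, SE 0.31). COR27 and AT4G33980 lay close to background in Col with water (means of 5.22 and 5.33), so the size of their changes depends on the pseudocount. AT2G15020 was lower (-4.11, SE 0.36), with a mean of 4.35 in mil4 sid2, an intensity under 16. Of 8 measured ATG genes, which act in autophagy, 5 were higher, ATG3, ATG8C, ATG8D, ATG8E and ATG8F (62.5%, against 6.5% of 13286 named genes, 1-sided Fisher's exact test, adjusted p = 0.00421 over 78 tests). The family call held under quantile normalization (adjusted p = 0.00236) and was lost without Col water replicate 4 (3 genes, 0.213). All mil4 sid2 arrays were hybridized on another day than the Col arrays, so day and genotype cannot be told apart here. The GAPDH 3′ to 5′ ratio differed between these groups as well, at 1.09 in mil4 sid2 and 0.854 in Col with water. For the mil4 by sid2 interaction, 3 of 9 PUB genes and 3 of 10 EXPA genes were higher (adjusted p = 0.0483 each), calls lost in 14 and 15 of 19 other settings.

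Probe sets that differed from each of the 5 other groups numbered 388 for Col with water (243 higher, 145 lower), 215 for mil4 with BTH, 59 for Col with BTH, 28 for mil4 sid2, 13 for sid2 and 8 for mil4 with water. For Col with water the mean difference was 4.06 for ORA47, 2.36 for AT1G78070 and -3.28 for COR27 on the log2 scale.

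A segment of chromosome linked to mil4, and differing from Col by descent, could place genes that are lower in mil4 under both treatments next to each other. Of 12224 genes in order, 102 were lower under both, and the largest number in a window of 50 neighbouring genes was 4. The median of the largest number over 10000 shuffles was 3, and the permutation p was 0.476, so no such segment was detected.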
